A study of Mus musculus with 2 samples.

How the data were processed

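Per the labels, total RNA was extracted from the inferior left lobe of the lung with Trizol, labelled with biotin by the True-Labeling AMP kit and hybridised to a SuperArray GEArray of 128 oligonucleotide spots. There were 2 arrays, 1 for wild-type mice and 1 for Abcg1-/- mice, both from males aged 8 months. Groups were taken from the sample titles. The series design gives 4 mice per group, which are represented by 1 array each.

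The per-array files deposited by the authors hold 1 value per spot, a linear intensity in arbitrary units. No header or label gives the scanner, the image software or a background correction, and these are not given in the sources used here. The largest intensity was 62528 in WT and 63597.5 in Abcg1-/-, close to the largest 16-bit value of 65535. In 6 lines over both files the tab after an 8-letter symbol was missing, and symbol and value were split after the letter 8. The authors' value table holds a ratio per spot, with scale and centring not stated in the labels. Setting it against the intensities showed it to be the spot minus the array's dimmest spot, divided by the mean of 5 housekeeping spots (Gapdh, Rps27a, B2m and both Ppia spots) minus the same dimmest spot. Values recomputed in this way differed from the deposited ratios by at most 5.5e-10 in WT and 5.3e-10 in Abcg1-/-. The median of the authors' ratio over panel genes was 0.0529 in WT and 0.358 in Abcg1-/-.

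Before the data were examined, the design, the gene lists, the rule for named genes and most alternatives were fixed. Intensities were background corrected with normexp (limma 3.58.1 in R 4.3.3, offset 50, all spots in the fit), taken to log2, averaged over the spots of a gene and quantile normalized between the arrays over the 112 panel genes and the 5 housekeeping genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The background limit of an array was the mean plus 2 SD of its 4 blank and PUC18 spots, 27932 in WT and 43009 in Abcg1-/-. This left 13 panel genes above the limit in WT and 34 in Abcg1-/-. PUC18 was taken as a negative control from its name. The control spots AS1, AS1R1, AS1R2 and BAS2C, whose meaning the labels do not give, were left out of gene counts. A gene above the limit on 1 array alone has a bound: its level there against the higher of its own level and the lowest normalized level above the limit on the other array (log2 14.88 in WT, 13.48 in Abcg1-/-). No fold of a gene is given where that bound is under 1 or where neither array is above its limit, while list medians at the bounds use bounds under 1 as they are. A gene counted as higher or lower at 2-fold or more. A spot at 95% or more of its array's brightest spot was called near the ceiling, a definition made after the data were seen.

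With 1 array per group no test was made, and the number of arrays limits the precision. Each of 15 gene lists with at least 3 members above the limit was described by the percentile of its median among 10000 random lists of the same size, matched on mean level in 3 classes, and the housekeeping genes formed the 16th list. The named genes were those with the largest difference in each direction among genes above the limit on at least 1 array (up to 12 each, 5 and 11 being found, at the bound where there was one), the housekeeping genes, 2 to 4 members of each list and the 5 brightest genes of each array, 35 in all. Any other gene was chosen after its values were seen, as were Il10ra, Itgam and Tnfrsf1b in the myeloid list and the genes that mark the ends of a row.

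All 117 gene symbols were matched to the RefSeq gene table of assembly GRCm38.p6, 11 of them as older names, and Il8ra matches 2 current names. No genome sequence was used and no coordinates are given. The calculation was tested on 20 simulated pairs of arrays of 112 genes without a filter on dim genes, with 10 genes raised and 10 lowered 4-fold and 10% noise. It recovered 98.5% of the raised and 97.5% of the lowered genes, and called 2.34% of the unchanged ones. The simulated arrays had no ceiling, raised as many genes as they lowered, and were read without the background limit. Their background was near the dimmest spot of each array and almost the same at every spot. Real blank and PUC18 spots had means of 18226 in WT and 34342 in Abcg1-/-, with SDs of 4853 and 4334. These rates therefore do not cover the counts made with the limit, genes near the ceiling or genes as dim as the blank spots.

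Alternatives were scaling to the array median or interquartile mean, subtraction of the blank and PUC18 mean, a log offset at the percentile 10 of the genes, no filter, only genes above the limit on both arrays, the authors' value table, thresholds of 1.5-fold and 3-fold, and a limit at 3 SD. In the subtraction, spots below the limit were set to the limit. Added after the data were seen were the deposited intensities as they stand, scaling to the housekeeping genes with spots near the ceiling kept, subtraction of the median of genes in the same row, a limit without negative spots that lie 8 places from a near-ceiling spot, and counts without a filter under other scalings.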

Results

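ABCG1 is a membrane transporter that moves cholesterol out of cells, macrophages among them. Per the series title and design, the question was how inflammatory markers differ between lungs of wild-type (WT) mice and lungs of mice lacking Abcg1 (Abcg1-/-). RNA came from the inferior left lobe of male mice aged 8 months on a chow diet. Each genotype was represented by 1 array carrying 128 oligonucleotide spots, which hold 112 inflammation genes, 5 housekeeping genes and control spots. The series design gives 4 mice per group, and the labels do not say whether 1 mouse or a pool of them was hybridised. With 1 array per group there are no replicates, so every difference given here describes 2 arrays, has no replicate check and carries no p-value. Abcg1 had 0 spots on the array, so the knockout could not be read from these data.

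Every one of the 112 inflammation genes gave a brighter spot on the Abcg1-/- array than on the WT array. The median panel gene had an intensity of 9942 on the WT array (quartiles 8302.5 and 13933) and 31104 on the Abcg1-/- array (quartiles 22502 and 48481). The median ratio was 2.65, from 1.01 for complement component C3 to 6.10 for the CC chemokine Ccl9. The 4 spots without a mouse target (3 blank spots and 1 PUC18 spot) were also brighter on the Abcg1-/- array, with a mean of 34342 ± 4334 (SD over 4 spots) against 18226 ± 4853, a ratio of 1.88. Of the 112 genes, 95 had a larger ratio than that and 17 a smaller one. The order of the genes was largely shared by both arrays, with a Spearman correlation of 0.80 across genes, which are not independent replicates.

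**Figure D1:**
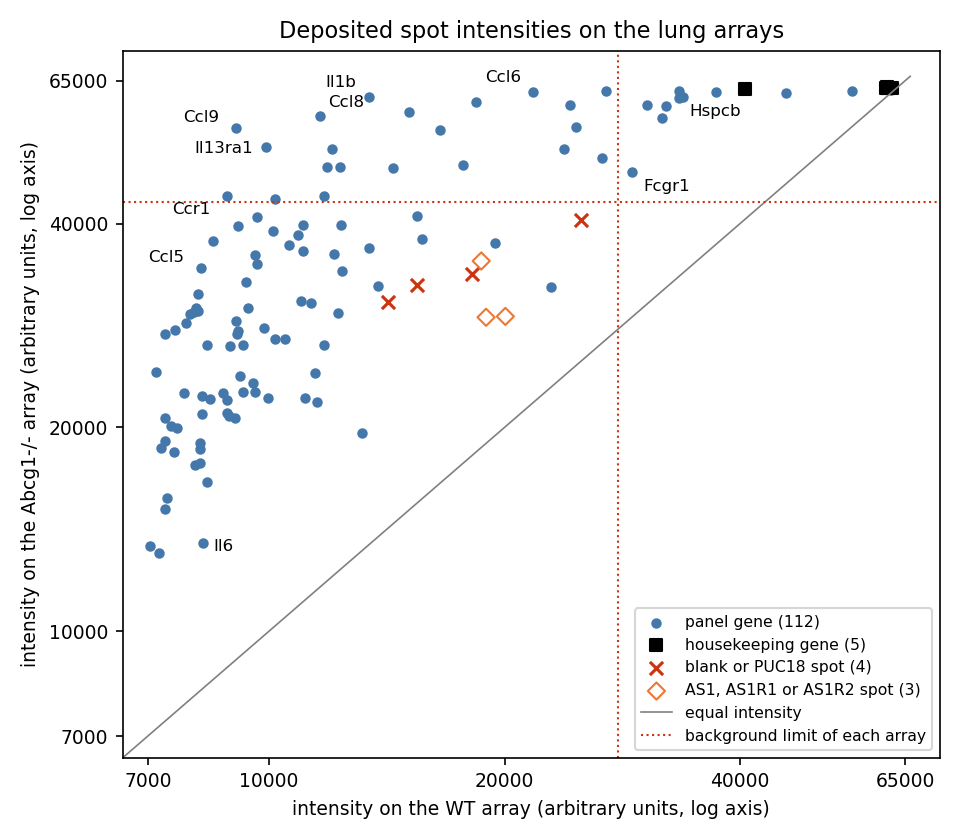
Deposited spot intensities in arbitrary units, WT array on the horizontal and Abcg1-/- array on the vertical axis, both logarithmic. Each point is a gene or a control spot, the grey line marks equal intensity and the dotted lines mark each array's background limit, 27932 for WT and 43009 for Abcg1-/-. All 112 panel genes lie above the line of equal intensity, as do the 4 blank and PUC18 spots.

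After background correction and quantile normalization, which gives both arrays the same distribution of levels, 1 gene above the background limit, Fcgr1, was at least 2-fold lower in the Abcg1-/- lung. Fcgr1, the high-affinity receptor for IgG on monocytes and macrophages, had a normalized log2 level of 14.88 on the WT array and 13.72 on the Abcg1-/- array, a 2.24-fold difference. Its direction depended on the scaling: the deposited intensity was higher on the Abcg1-/- array (47649.9 against 29145 in WT, where it lay just above the limit), and so was the authors' own value (0.686 against 0.404). The count of genes at least 2-fold higher was 0, and the rule allowed no other outcome, because the brightest panel gene on the Abcg1-/- array lay only 0.70 (log2) above the lowest level that passed the limit in WT, while differences of up to 2.12 could be read downward. The split of genes higher against lower moved with the scaling and with this reach. It was 0 against 13 with each array scaled to its median, where again no gene could count as higher, and 13 against 0 in the authors' values and 6 against 0 in the deposited intensities, where no gene could count as lower. Quantile normalization cannot show a shift of the whole panel.

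Only 13 of the 112 genes were above the background limit on both arrays. They are described here as bright spots, and how abundant their transcripts were was not tested. C3, the lung chemokine Cxcl15 and Il6st, the signalling subunit shared by receptors of the IL-6 family, lay near the ceiling of the scanner on both arrays, with WT intensities of 62349, 61528 and 61599, so that no difference can be read for them. Another 6 were near the ceiling on the Abcg1-/- array alone, which leaves their level there, and the direction after normalization, open. These were osteopontin (Spp1), a secreted phosphoprotein made by macrophages among other cells (33388 in WT, 62877 in Abcg1-/-), the IL-10 receptor subunit Il10rb (55607 and 62844), the cytokine Mif (45747 and 62373), the Fc receptor gamma chain Fcer1g (37257 and 62665), platelet factor Cxcl4 (33835 and 61426.5) and the IL-12 subunit Il12a (33467 and 61326). Below the ceiling on both arrays were 4 genes. Besides Fcgr1, their normalized log2 differences (Abcg1-/- minus WT) were -0.39 for Blr1 (now Cxcr5, the B cell receptor for Cxcl13), -0.29 for Ccl21a, a ligand that draws T cells and dendritic cells into lymphoid tissue, and -0.14 for the IL-6 receptor Il6ra. In the deposited intensities all 4 were brighter on the Abcg1-/- array. Il6ra (59884) and Ccl21a (59747) lay just under the near-ceiling cut of 60418 there, so their differences may be compressed too. In the spot order Blr1 stands between Gapdh and C3, and Il6ra stands beside Il6st, all 3 near the ceiling.

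A further 21 genes were above the limit on the Abcg1-/- array alone, and 0 were above it on the WT array alone. They included the myeloid chemokines Ccl9 (intensity 9075 in WT, 55366 in Abcg1-/-) and Ccl6 (21779 and 62559), the monocyte attractant Ccl2 (16536 and 54992), the neutrophil attractant Cxcl2 (15118 and 58552), and the cytokines Il1b (13419 and 61449) and Il18 (26949.6 and 62800.0). Receptors among them were Ccr1 (8825 and 43977), Ccr2 (12048 and 51492.5) and Il13ra1, a subunit of the IL-13 receptor (9903 and 51867). Over the whole panel the intensity ratio exceeded that of the blank and PUC18 spots for 95 of 112 genes. It did so for 20 of the 21 genes, the exception being the chemokine Cxcl14, whose ratio was just below it. Passing the limit on the Abcg1-/- array alone already selects for a high ratio. Because the WT spots lay below the limit, these genes have only a lower bound on the normalized scale. The bound was at least 1.2-fold for Il18, 1.12-fold for Ccl6, 1.08-fold for Il1b and 1.0-fold for Tollip, an inhibitor of Toll-like receptor signalling, while for the other 17 it was under 1 and no fold is given. On the Abcg1-/- array Il18, Ccl6 and Il1b were near the ceiling, and Tollip (60410.3) lay just under the cut of 60418. Their normalized levels there rest on small differences between bright spots, so these bounds are uncertain. With each array scaled to its median, the differences of Il18, Ccl6 and Tollip turned to -0.93, -0.50 and -0.20, while that of Il1b was 0.66. These are differences between spot levels and not bounds. The remaining 78 genes were not above the limit on either array.

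Median log2 differences of the gene lists were taken over members above the limit on at least 1 array, and most of these were below the limit in WT, so that the medians describe spot levels and are given with members at their bounds as well, bounds under 1 included. A median at the bounds is the lowest that dim WT spots allow under this normalization, and where it is under 0 the direction is open. It does not cover other scalings or WT levels near the ceiling. Among chemokine ligands, 9 of the 19 CC genes were above the limit, of which Ccl21a alone passed it in WT. Their median was 0.20 (SD over members 0.93), higher than 30.1% of 10000 random gene lists matched on level, and -0.51 at the bounds. Ccl9 had the largest intensity ratio of the panel, while Ccl19, which guides cells to lymphoid tissue, went from 23859.7 in WT to 51577 and Ccl17 from 24220.5 to 59839.7. For the 12 CXC and CX3C ligands, 5 were above the limit, Cxcl15 and Cxcl4 in WT too, and their median of 0.00 is the value of Cxcl15, which the ceiling fixes, so that it gives no information on the list. The 16 chemokine receptors had 4 members above the limit, Blr1, Ccr1, Ccr2 and Il8ra, and a median of 0.30 (SD 1.04, percentile 22.4; -0.995 at the bounds). In the authors' values the medians of these lists were 1.87, 1.04 and 2.72, and with each array scaled to its median they were -0.50, -1.40 and 0.27.

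Interleukins were mostly dim, with 3 of 22 above the limit, Il1b, Il18 and Il12a, of which only Il12a passed it in WT. All 3 were near the ceiling in Abcg1-/-, so their median of 0.35 (SD 0.69; 0.11 at the bounds) is given without a rank. The 12 interleukin receptor genes had 6 members above the limit, 3 of them in WT too, and a median of 0.28 (SD 0.74, percentile 70.0) that was -0.48 at the bounds. The 0.28 lies midway between Il1r2 and Il6st. The ceiling on both arrays fixes the value of Il6st, so this rank says little. Classical pro-inflammatory genes had 4 of 13 members above the limit, Il1b, Cxcl2, Ccl2 and Il18, all in Abcg1-/- alone and 2 of them near the ceiling there, with a median of 0.55 (SD 0.47, percentile 97.46) that was -0.05 at the bounds. Anti-inflammatory and regulatory genes had a median of 0.56 over 3 of 7 members (SD 0.48, percentile 83.7) and -0.27 at the bounds. These were Il10rb, Tollip (18400 in WT, 60410.3 in Abcg1-/-) and the decoy IL-1 receptor Il1r2 (11857 and 48509). Scaling to the array median turned the interleukin, interleukin receptor and anti-inflammatory medians to -0.93, -0.36 and -0.20, and took the pro-inflammatory median to 0.04.

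Lists with fewer than 3 members above the limit have no percentile for those members. In the TNF ligand and receptor family of 6 genes, 1 was above the limit, and in Abcg1-/- alone, the lymphotoxin subunit Ltb (24670.2 in WT, 55504 in Abcg1-/-). Type 2 immunity genes had 2 of 14 above it, Il13ra1 and Ccl17, also in Abcg1-/- alone. Interferon-gamma and type 1 immunity genes had 2 of 11, Il18 in Abcg1-/- alone and Il12a on both arrays. The complement, acute phase and extracellular mediator list of 5 genes had Spp1, Mif and C3 above the limit on both arrays, all near the ceiling in Abcg1-/-. Their median of -0.10 is the value of C3, near the ceiling on both arrays, and no difference can be read from it.

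Markers of macrophages and other myeloid cells had a median of 0.98 over 6 of 12 members (SD 0.82, percentile 97.0). The 6 were Ccl9, Ccr1, Il1b, Ccr2, Ccl6 and Spp1, of which only Spp1 was above the limit on both arrays, and 3 (Il1b, Ccl6 and Spp1) were near the ceiling in Abcg1-/-. The median was 0.49 with the blank and PUC18 mean subtracted, 0.50 with the median of row-mates taken off, 0.64 with each array scaled to its median and 3.05 in the authors' values. With members at their bounds, under 1 for Ccl9, Ccr1 and Ccr2, the median was -0.20. Over all 12 members the median was 0.58 (SD 1.27), higher than 98.9% of random lists, with 9 members above 0 and 3 below it. The 3 were the IL-10 receptor Il10ra, the integrin Itgam and the TNF receptor Tnfrsf1b, none of which was above the limit on either array. Fcgr1, the receptor on monocytes and macrophages named above, was not on the list fixed beforehand. It was above the limit on both arrays and went the other way on this scale, at -1.16. The all-member median lay above the median of the panel by 0.67, and by 0.04 to 0.74 under the other 6 scalings tried. The 0.04 came with the blank and PUC18 mean subtracted, where spots below the limit share 1 value. The 0.74 is the same value for median, interquartile mean and housekeeping scaling, which shift all genes of an array alike. Spots of 4 members stood together in the part of the spot order with the highest differences, the 8 genes from Ccl5 to Ccr3, whose median difference was 1.49.

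Neutrophil markers and attractants had a median of 0.28 over 4 of 9 members, Cxcl2, Il1r2, Cxcl15 and Il8ra (SD 0.42, percentile 49.9; -0.62 at the bounds). The 0.28 lies midway between Il1r2 and Cxcl15. The ceiling on both arrays fixes the value of Cxcl15, so this rank says little. The neutrophil median was 0.07 with each array scaled to its median and 2.5 in the authors' values. B cell and lymphoid follicle markers had a median of -0.29 over 5 of 8 members (SD 0.31, percentile 3.54). The 5 were Ccl19, Blr1, Ccl21a, Ltb and Cxcl13, the ligand of Blr1 (11750.1 in WT, 43928 in Abcg1-/-), of which Blr1 and Ccl21a were above the limit in WT too. At the bounds the B cell median was -0.39, and in the authors' values and the deposited intensities it was above 0, at 1.31 and 1.11. T and NK cell markers had 1 of 11 members above the limit, Ltb.

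**Figure D2:**
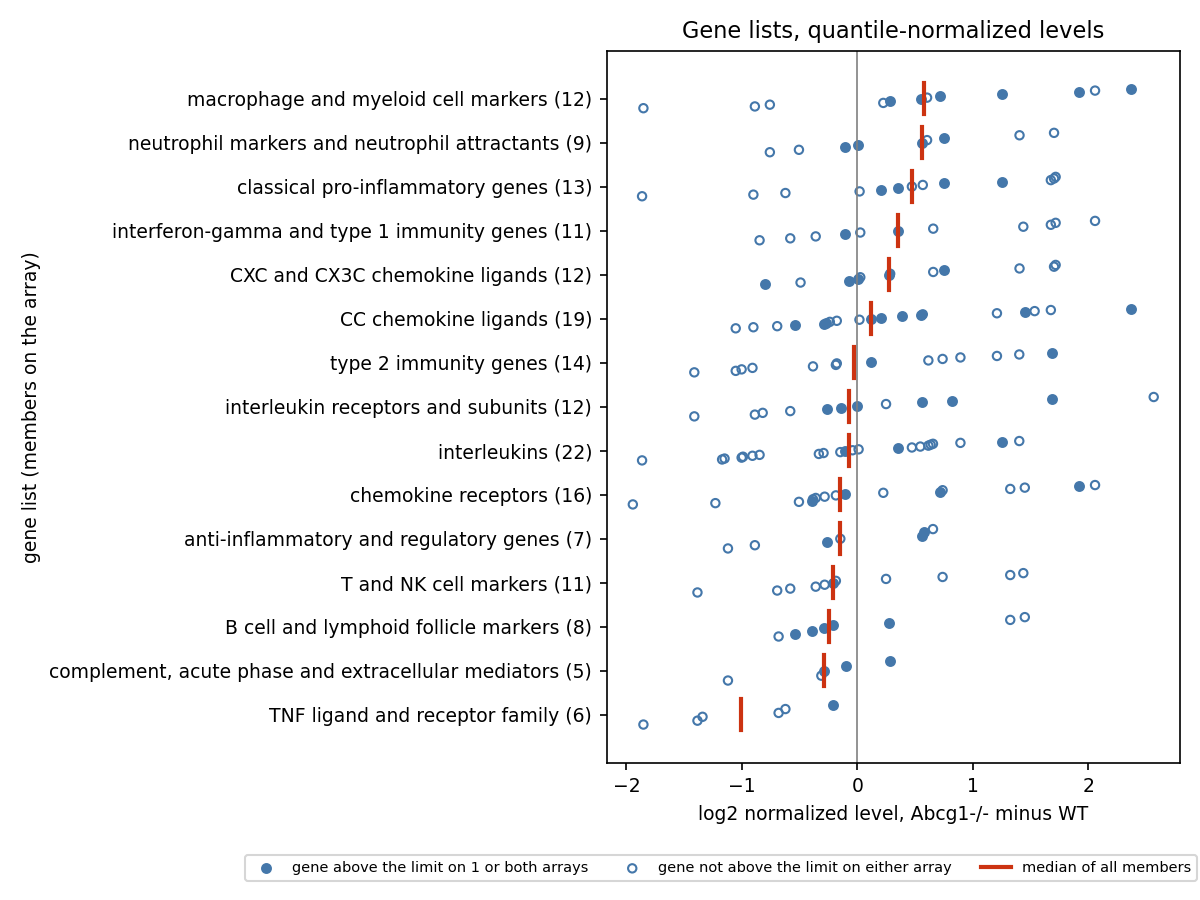
Normalized log2 level on the Abcg1-/- array minus the WT array (horizontal axis) for each member of the 15 gene lists other than the housekeeping genes, with filled points for genes above the background limit on 1 or both arrays, open points for the rest and a red bar at the median of all members. On this scale the median of all members runs from -1.01 for the TNF family to 0.58 for macrophage and myeloid cell markers, an order that other scalings change.

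The housekeeping genes Gapdh, Rps27a, B2m and Ppia were near the ceiling on both arrays, with a mean over their 5 spots of 61805 ± 545 (SD) in WT and 63517 ± 73.7 in Abcg1-/-. Hspcb (now Hsp90ab1, a heat shock protein) was below the ceiling in WT at 40624 and near it in Abcg1-/- at 63274.5. The median of the 5 genes was 0.00 after quantile normalization and -2.36 with each array scaled to its median. Near the ceiling lay 3 panel genes in WT and 12 in Abcg1-/-, so that differences of the brightest genes are compressed. At the dim end, 84 genes in WT and 55 in Abcg1-/- were dimmer than every blank spot.

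**Figure D3:**
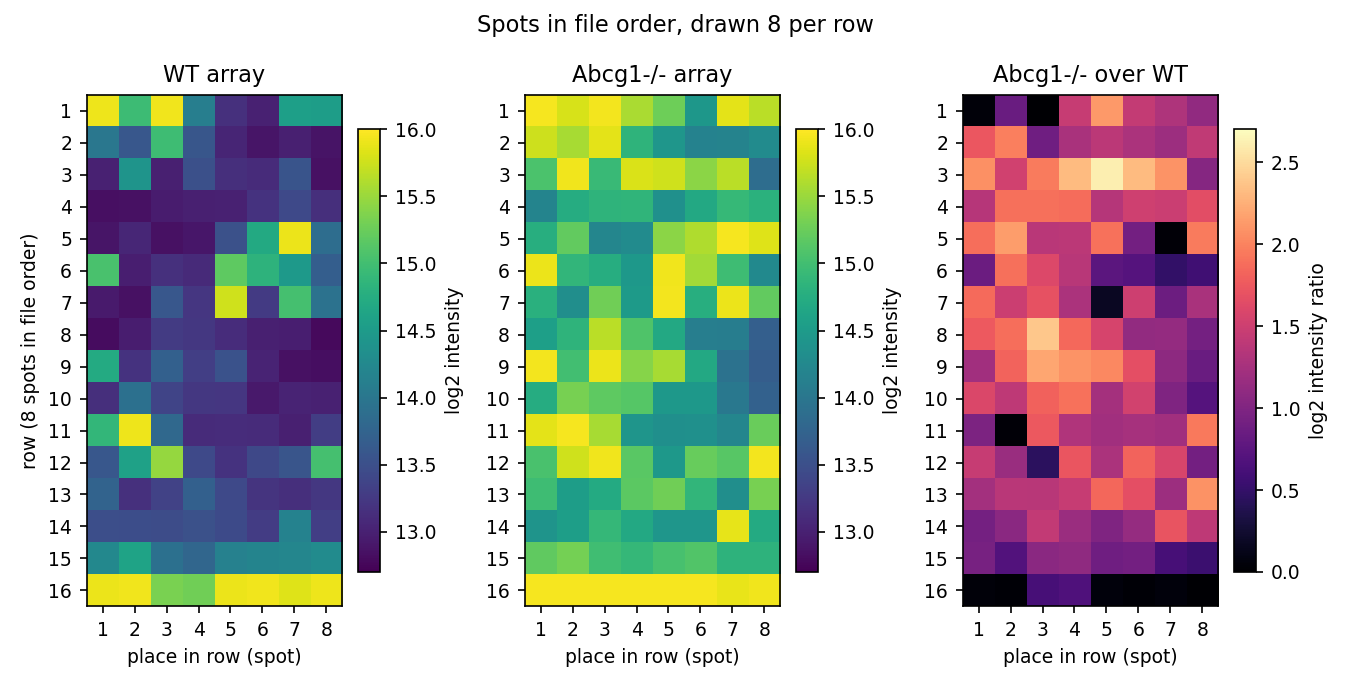
Log2 spot intensity of the 128 spots of the WT array and the Abcg1-/- array and their log2 intensity ratio, in file order and drawn 8 spots per row, an arrangement inferred from the data. The ratio is highest in row 3, where the normalized median difference is 1.49, and the log2 ratio is near 0 where WT spots are already near the ceiling, as in row 16 apart from its 2 Hspcb spots.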

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

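All tests in this part were chosen after the result was seen. Spots outside the gene comparisons carried signal that differed between the arrays. The 4 blank and PUC18 spots had a mean of 34341.8 on the Abcg1-/- array against 18226 on the WT array. The 3 spots named AS1, AS1R1 and AS1R2, whose content the labels do not give, had a mean of 31157.1 ± 3520 (SD over 3 spots) against 19222 ± 728. These spots drew attention because they hold no panel gene and still moved with the array.

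The pattern to weigh is that the Abcg1-/- array was brighter at every gene spot. The authors' scaling does not remove it: all 5 spots they divide by lie near the ceiling on both arrays, and the blank and PUC18 spots keep a ratio of 2.07 in the authors' values, consistent with a scaling that cannot follow the overall brightness. Exposure or amount of label alone would act on all spots through one curve. The 7 blank, PUC18 and AS1 spots had a mean on the Abcg1-/- array of 0.66 of that of the 13 genes in the same WT range (32977 against 49949). Of 10000 random sets of 7 of those genes 0 were as low, but sets drawn from 13 genes overlap heavily. These values argue against one curve only if control spots and genes are otherwise alike. Light from near-ceiling spots may have raised the control spots in WT, which would lower their ratio. In WT, 2 of the blank and PUC18 spots, AS1R2 and AS1 lie 8 places from a near-ceiling spot. That light was not separated here, so exposure or label alone is not settled by this comparison. The control spots stand next to each other, so a lower brightness at that place of the array stays open, alone or with a longer exposure. Of the genes of that WT range next to them at 8 spots per row, Xcr1 had 37452 and Tollip 60410.3 on the Abcg1-/- array, which go opposite ways. Tollip had the highest normalized difference of its row, however. The median normalized differences of the 2 rows, -1.36 for row 14 and -1.23 for Xcr1 in row 15, were the lowest of the layout. In median intensity ratio row 6 was lower still, at 1.75, followed by row 15 at 1.93 and row 14 at 2.23. These row values go with a lower brightness at that place, though in intensity ratio it was not the lowest. A rise of inflammatory transcripts in the Abcg1-/- lung also stays open and was not tested, since genotype and array are the same thing here.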

How the results depend on the processing

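The deposited intensities as they stand, the housekeeping scaling with spots near the ceiling kept, the row correction, the limit without some negative spots and the counts without a filter under other scalings were chosen after the data were seen. With no replicates, a list median was taken as moved when it shifted by more than 1 SD over its members, and a count when it changed by over 1.5 times. Where no reason is named, the cause was not tested. The count of 1 gene at least 2-fold lower held with the offset at the percentile 10, with only genes above the limit on both arrays and at 1.5-fold. The lower count was 0 at 3-fold, with the limit at mean plus 3 SD and with the blank and PUC18 mean subtracted. Without a filter on dim genes it was 18 higher and 17 lower, of which 13 and 16 were below the limit on both arrays and 5 of the higher ones were above it in Abcg1-/- alone, where the bound no longer applied. The anti-inflammatory median was then -0.15, and those of chemokine receptors, interleukins and interleukin receptors turned to -0.15, -0.08 and -0.07. The count of 0 genes higher says nothing about stability: with the limit, no gene could count as higher in the main setting, with median or interquartile mean scaling, with the offset, at 3-fold or at mean plus 3 SD. It was also 0 at 1.5-fold and with the blank and PUC18 mean subtracted, where a call was possible only by a small margin. At 1.5-fold the largest log2 rise that could be read was 0.70, against a threshold of 0.585. Of the panel genes, only Cxcl15, Il6st and C3 were bright enough on the Abcg1-/- array, and they lay near the ceiling in WT too. With the subtraction the largest readable log2 rise was 1.07, just over 2-fold, so neither count says much about stability. No gene could count as lower in the authors' values or the deposited intensities. Interleukin receptors turned to -0.14 over genes above both limits and to -0.04 with the blank and PUC18 mean subtracted, and chemokine receptors to -0.11 at mean plus 3 SD. The planned scaling to housekeeping genes below the ceiling gave no value, since none was below it on both arrays. Quantile normalization as an alternative is the main setting. Taking off the row median moved none of the 10 list medians by more than their SD. It did change the sign of 3 of them, interleukins to -0.34, chemokine receptors to -0.01 and the complement list to 0.02, and took the myeloid median from 0.98 to 0.50. Of the 4 negative spots, 2 lie 8 places from a near-ceiling spot in WT and all 4 do in Abcg1-/-. Without those 2 the WT limit was 16611 in place of 27932, 23 genes in place of 13 passed it, and 2 genes were lower (Fcgr1, and Gpr2 at its bound) and 0 higher, where a call was possible. The chemokine receptor median turned to -0.25. Signal over background is 1 limit of these arrays, as 99 panel genes in WT and 78 in Abcg1-/- were not above the background limit, beside the ceiling, the scaling and the single array per group.

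Scaling each array to its median gave 13 genes lower, a median of -0.87 over all genes above the limit (0.06 in the main setting) and -2.36 for housekeeping genes. List medians were then -0.50 for CC ligands, -0.36 for interleukin receptors, -1.40 for CXC ligands, -0.93 for interleukins, 0.04 for pro-inflammatory genes, -0.20 for anti-inflammatory genes, -1.11 for B cell markers and -1.90 for the complement list. The interquartile mean gave 13 lower and, in the same order, -0.84, -2.33, -0.47, -0.33, -1.37, -0.90, 0.07, -0.17, -1.08 and -1.87. The chemokine receptor, myeloid and neutrophil medians stayed above 0, at 0.27, 0.64 and 0.07 with median scaling. With the interquartile mean they were 0.30, 0.67 and 0.10. With the authors' values, 13 genes were higher and 0 lower, with a median of 1.5 over all genes. The list medians were 1.87 for CC ligands, 1.04 for CXC ligands, 2.72 for chemokine receptors, 1.44 for interleukins, 2.06 for interleukin receptors, 2.44 for pro-inflammatory genes, 2.18 for anti-inflammatory genes, 3.05 for myeloid, 2.5 for neutrophil and 1.31 for B cell markers, and 0.47 for the complement list. Fcgr1 reversed there to 0.76. The deposited intensities gave 6 higher and 0 lower, with 1.26 over all genes, Fcgr1 reversed to 0.71, and list medians in the same order of 1.52, 0.91, 1.92, 1.22, 1.51, 1.84, 1.72, 2.15, 1.85, 1.11 and 0.45. The housekeeping scaling gave 5 higher and 0 lower, with 1.35 over all genes, Fcgr1 reversed to 0.53, and list medians of 1.72, 0.82, 2.49, 1.30, 1.86, 2.26, 2.02, 2.87, 2.29, 1.11 and 0.32. Without a filter the counts were 20 higher and 32 lower with median scaling, 97 higher and 1 lower in the authors' table, 89 and 0 in the deposited intensities, and 2 and 0 with the blank and PUC18 mean subtracted. Of 39 single genes above the limit, housekeeping genes included, 8 changed sign with median scaling and 14 in the authors' values. Il18, Ccl6 and Tollip, with bounds of 1-fold or more in the main setting, turned to -0.93, -0.50 and -0.20 with median and -0.90, -0.47 and -0.17 with interquartile mean scaling. Il1b, the other gene with such a bound, stayed above 0, at 0.66 and 0.69.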

Other observations

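All tests in this part, and the choice of the genes it names, came after the data were seen. The medians over all members of lists with at least 3 members above the limit belong to the planned setting without a filter. The 9 Toll-like receptors on the array, sensors of microbial products, were not above the background limit on either array, so no fold is given for them. Spot intensities were 11512.5 in WT and 21831 in Abcg1-/- for Tlr8, an endosomal receptor for RNA, 11462 and 24040.1 for Tlr9, the receptor for bacterial DNA, and 9659 and 40927 for Tlr7. All 9 spots were brighter on the Abcg1-/- array. As a description of dim spots, the median of their normalized log2 differences was -0.67 (SD 0.92), higher than 6.41% of random lists. Their spots follow each other in rows 13 and 14 of the inferred layout, which had row medians of -0.58 and -1.36, so position was not separated from the family.

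Other genes below the limit on both arrays included several chemokine and type 1 immunity genes whose intensity ratios were above the panel median of 2.65. Intensities were 7162 in WT and 24107 in Abcg1-/- for the IL-12 receptor subunit Il12rb2, 8484.5 and 37692 for the interferon-induced Cxcl10, 7575 and 27850.3 for Cxcl1, 8189.8 and 34413 for the T cell and monocyte attractant Ccl5, and 7832 and 28522 for Ifng. With dim genes included, and so as a description of spots, the median log2 difference of all 11 interferon-gamma and type 1 members was 0.35 (percentile 89.7; 56.2 to 88.4 in the 5 scalings named below), while in the deposited intensities the list lay at the median of the panel (1.41 for both, percentile 56.2). It was 0.47 for pro-inflammatory genes (94.4; 62.9 to 95.5), 0.56 for neutrophil genes (92.2; 71.8 to 98.9), 0.28 for CXC ligands (88.0; 83.6 to 91.4), 0.12 for CC ligands (83.6; 68.4 to 90.5), -0.03 for type 2 immunity genes (56.0; 30.3 to 55.9), -0.07 for interleukin receptors (53.4; 19.4 to 39.9), -0.08 for interleukins (51.6; 51.2 to 64.2), -0.15 for chemokine receptors (39.2; 72.0 to 77.5), -0.15 for anti-inflammatory genes (34.2; 50.7 to 85.3), -0.21 for T and NK cell markers (34.2; 35.2 to 47.6), -0.25 for B cell markers (22.9; 22.2 to 46.5) and -0.29 for the complement list (18.8; 5.7 to 20.3). The ranges are percentiles with median, interquartile mean and housekeeping scaling, in the deposited intensities and in the authors' values. Median, interquartile mean and housekeeping scaling shift all genes of an array alike, so they are not separate checks of a rank. The ranges lie wholly above the percentile after quantile normalization for chemokine receptors, anti-inflammatory genes and T and NK cell markers. They lie wholly below it for interleukin receptors, interferon-gamma and type 1 genes and, by a small margin, type 2 immunity genes. With the blank and PUC18 mean subtracted, the medians of these lists equalled that of the panel. That equality gives no information, because spots below the limit were set to the limit there and most genes share 1 value. At the other end stood the interferon gene Ifna2 (13128 in WT, 19623 in Abcg1-/-), the chemokine receptor Gpr2 (22941 and 32230.5) and the cytokine Il6 (8241 and 13495). In the authors' values Il6 was 0.0219 in WT and 0.00891 in Abcg1-/-, and it was the only panel gene at least 2-fold lower there, leaving out Il20, which is listed at 0 in Abcg1-/-.

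Over all members and after quantile normalization, the myeloid list had the highest median and the TNF family the lowest (-1.01, percentile 1.65), but in the deposited intensities the neutrophil list stood above the myeloid one (1.88 against 1.78), and the complement list stood below the TNF family with median scaling (-1.33 against -1.20), interquartile mean scaling (-1.30 against -1.16), housekeeping scaling (0.895 against 1.03), the deposited intensities (0.913 against 1.17) and the authors' values (1.04 against 1.68). Median, interquartile mean and housekeeping scaling differ by a constant per array, so for the order of lists they are the same result. Position is a candidate explanation for the myeloid list: with 8 spots per row, taking off the median of row-mates lowered its median from 0.58 to 0.19 (SE over members 0.25), and 6 of 12 members stayed above their row-mates. For the TNF family the same step left -0.28 of -1.01 (SE 0.17), which decides nothing, as 4 of its 6 members share 1 row. Light from a brighter neighbour may add to the myeloid values, but of the 4 members at least 2-fold higher a share of 0.25, Il1b alone, was brighter than all its neighbours, so this stays open as well. The spot order follows the alphabet, so related genes share rows (chemokines and their receptors in row 3, Toll-like receptors beside TNF family members in row 14), and position and a shared change of these genes in the Abcg1-/- lung cannot be told apart for the TNF family and stay open for the myeloid list.

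Neighbouring spots were alike in brightness: log2 intensities of spots 1 place apart correlated at 0.57 in WT and 0.43 in Abcg1-/- across spots, and at 8 places at 0.31 and 0.15. Light of near-ceiling spots reaching nearby spots may contribute, but no test here decides it. The 11 spots 8 places from a near-ceiling WT spot were brighter than 108 others by a median of 0.99 log2, yet the layout of 8 per row was itself inferred from brightness at 8 places, and the excess was 0.95 at 2 places and 0.78 at 7. It was largest at 1 place, at 1.53, a distance that does not rest on the inferred layout but at which related genes also stand together. Related genes standing near each other in the alphabet stay open as well. Such light would also raise the background limit, since 2 of the 4 blank and PUC18 spots lie 8 places from a near-ceiling WT spot.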
